A study of Mus musculus with 19 samples.

How the data were processed

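The study measured gene expression by RNA-seq in mouse glial progenitor cells (GPC) and glia derived from embryonic stem cells, and binding of the transcription factors SOX3, SOX9 and NFIA in GPC by ChIP-seq. Per the labels' protocols, the stem cells were differentiated with all-trans retinoic acid, cells with the surface antigen A2B5 were sorted magnetically, and these were grown with EGF and FGF2. The labels carry the same protocol text for GPC and glia, so how the glia were made is not given in the sources used here. RNA libraries were made with a TruSeq RNA kit and ChIP libraries with a TruSeq ChIP kit, per the labels' protocols. The SOX3 antibody came from the authors' laboratory and the SOX9 and NFIA antibodies from commercial suppliers. The labels describe 19 samples, of which 4 GPC and 3 glia RNA libraries and 2 SOX3, 3 SOX9 and 2 NFIA ChIP samples entered through the processed files. The 2 input samples and 3 samples of the histone mark H3K27Ac were not analysed here.

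The expression table holds read counts per gene as deposited by the authors, as whole numbers without normalization, and the file headers give the mapped reads of each library. RPKM values per gene were computed by the authors, scaled by the length of the gene model and the reads of the library, per the file headers. The RPKM values served for levels only, and all expression tests used the counts. The genome build was mm9, per the submitters' processing notes. The aligner, the counting tool and whether counting used strand are not given in the sources used here, so reads of overlapping or antisense genes and of near-identical copies cannot be told apart. Of the 22958 genes in the table, 527 symbols were repeated and 170 were joined from several symbols, and each line was kept as its own gene. The counts came to 80.9% to 83.1% of mapped reads, and the 10 most abundant genes took 3.84% to 4.32% of them.

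MACS and MACS2 are named as peak callers, per the submitters' processing notes. The peak names in the deposited lists begin with MACS for SOX3 and carry MACS2 and merged libraries for SOX9, and the caller behind the NFIA list is not given in the sources used here. Each factor had 1 list over all its samples, so replicates could not be compared. The SOX3 and SOX9 lists pair each peak with a gene and a signed distance to its TSS, assigned by the authors in a manner not given in the sources used here. The NFIA list carries a score per peak as deposited by the authors, between 14 and 1677, and what it measures is not stated. SOX3 peaks were 57 to 1650 bp wide, SOX9 peaks 601 bp and NFIA peaks 282 to 301 bp, with a median of 301 bp. Peak numbers ran to 1819 for SOX3 and 3086 for SOX9, above the 1367 and 2943 peaks listed, and the reason is not given in the sources used here. The NFIA list had no genes assigned, so NFIA entered the tests near genes only through its overlap with SOX9 peaks, and 4 tests near changed genes were run in place of the 6 laid out at first. Gene symbols of the peak lists were matched to the expression table directly or through synonyms in a RefSeq table of assembly GRCm38.p6, which was used for names only. For SOX3 1220 peaks matched directly, 26 through a synonym and 121 not at all, and for SOX9 2653, 85 and 205.

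Counts were tested in R 4.3.3 with edgeR 4.0.16, with TMM scaling, the default filterByExpr filter, which left 13588 genes, and robust quasi-likelihood fits (glmQLFit and glmQLFTest) of glia against GPC. P-values were adjusted by Benjamini-Hochberg and called at 0.05, two-sided. The standard error of a log2 change was taken as its size over the square root of the F statistic. The common biological coefficient of variation was 0.108. Counts of replicate pairs differed by more than sampling noise in every pair, with a chi-square per gene of 2.05 to 3.59 among GPC replicates 1, 2 and 4, 25.8 to 29.9 in pairs with GPC replicate 3, and 4.33 to 10.0 among glia.

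Of 25 gene lists fixed from general knowledge, 24 had measured members, and mitochondrially encoded genes had none. They covered astrocytes, maturing oligodendrocytes, oligodendrocyte precursors, neural progenitors, the cell cycle, FGF and MAPK feedback, BMP targets, Notch, neurons, pluripotent cells, microglia, mesenchyme, endothelium, Schwann cells and neural crest, endoderm and epithelium, ependyma, reactive astrocytes, cholesterol synthesis, the SOX and NFI families, immediate early and stress genes, Hox genes, ribosomal proteins and histones. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 24 lists, and again with the correlation estimated. Members were also adjusted over the list alone. limma's fry, which asks whether a list's members move on balance in 1 direction and does not compare them with other genes, gave an unadjusted p of 0.471 for the SOX family and at most 0.0430 for each other list. Genes named in the text were chosen by a rule. It took Sox3, Sox9, Nfia, Sox2 and Sox10, then the 8 rising and 8 falling genes of largest log2 change among those past the threshold, without overlap between the groups' libraries and with a mean in the higher group in the upper part of tested genes (above the median). For the astrocyte, oligodendrocyte, precursor, progenitor, cell cycle and neuron lists it took the 3 largest changed members in each direction, for the other lists 1, and for each peak list the 3 peaks of highest score or, with no score, of largest width. This gave the 70 genes counted here, and a few further genes are not reported here.

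Peaks were compared in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and drawn with matplotlib 3.10.9. Peaks that shared at least 1 bp counted as overlapping. Each listed peak was counted on its own, also where SOX9 peaks overlapped each other, so peaks can outnumber regions. Each overlap was set against 1000 random placements of the peaks within their chromosomes, one-sided. A peak was assigned to the gene the authors gave if its distance to the TSS was at most 100 kb, and shares of genes or peaks were compared by two-sided Fisher's exact tests with 95% intervals, with genes that did not pass the expression test as background for changed genes. Logistic regressions took mean log2 CPM, computed from the counts, as a covariate. Tests near lists were adjusted over 48 pairs of list and factor.

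The groups, main tests, gene lists, naming rule and the alternatives below were fixed before the data were examined. They were DESeq2 (version 1.42.0) size factors, the DESeq2 Wald test, no filter, a filter of 50 counts in 3 libraries, a replicate block with GPC replicate 4 left out, leaving out each library, an estimated correlation for lists, peak shifts of 10 to 100 kb, other overlap rules, halved SOX3 and NFIA lists, a limit of 20 kb, a TSS distance of 5 kb and genes changed at least 2-fold. Alternatives chosen after seeing the data were the removal of densely filled 2 Mb windows, of chromosome 13 from 20 to 24 Mb or of peaks near a TSS, the restriction to SOX9 peaks that overlapped NFIA or SOX3, mean expression as a covariate, and for the tests near lists the 20 kb limit. Some results were not among the tests laid out at first. These were NFIA overlap with and without the other SOX factor, NFIA scores by SOX9 overlap and SOX9 against SOX3 shares near a TSS. The direct comparison of rising and falling genes and the random lists matched on expression or length were also not among them.

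The steps were checked on simulated data. In simulated glia against GPC 200 genes were changed and 13434 genes were tested. Of the changed genes that were tested, 62.7% of 67 changed 1.5-fold, 87.9% of 66 changed 2-fold and 100% of 66 changed 4-fold were recovered, with 10 false calls (5.68% of calls). A simulated list of 20 genes raised 1.5-fold gave a camera p of 4.45e-35, and 20 unchanged genes gave 0.168. The simulated genes were drawn independently and no simulated library was set apart. In the real data 70.4% of genes changed and GPC replicate 3 stood apart. The simulated rates of recovery and false calls therefore need not hold for the real comparison. In simulated lists of 1000 peaks, 200 planted overlaps gave 189.6 overlaps above the random mean with a permutation p of 0.001, and none planted gave 6.96 with a permutation p of 0.101. Motifs, sequence under peaks and the position of peaks within genes were not analysed here.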

Results

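RNA was sequenced from mouse embryonic stem cell (ESC)-derived glial progenitor cells (GPC), dividing cells that give rise to astrocytes and oligodendrocytes, and from ESC-derived glial cells, called glia here. The comparison asks which genes differ between progenitors and glia. The chromatin immunoprecipitation (ChIP-seq) peaks ask where the transcription factors SOX3, SOX9 and NFIA were bound in the progenitors relative to each other and to those genes. There were 4 GPC and 3 glia RNA libraries, and 1 peak list for each factor, from 2 SOX3, 3 SOX9 and 2 NFIA samples, all GPC. Reads counted in genes came to 12836998, 13037426, 22439837 and 12927131 in GPC replicates 1 to 4, and to 17166532, 6897294 and 17369367 in glia replicates 1 to 3. The labels number the replicates without saying whether they came from separate cultures, so p-values measure the spread between these samples, which may be technical.

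Most measured genes differed between GPC and glia. Of 13588 genes tested, 4789 rose and 4779 fell in glia, together 70.4% of them (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05, two-sided). Changes of at least 2-fold were found for 2236 rising and 1255 falling genes, and changes of at least 8-fold for 454 rising and 105 falling genes. In 9440 genes (69.5%) the 4 GPC and 3 glia values did not overlap, where chance gives 5.71%. The first principal component held 90.4% of the variance and separated GPC from glia. The second held 4.48% and set GPC replicate 3, which was also the deepest library, apart from the other 3 GPC libraries.

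Transcripts of the factors profiled by ChIP-seq moved in different directions, with Sox3 lower and Sox9 and Nfia higher in glia. Sox3, a SOX factor of neural progenitors, fell from 82.4 ± 26.4 RPKM (SD, n = 4) to 39.2 ± 8.91 RPKM (n = 3), a log2 change of -1.09 ± 0.26 (SE). Its GPC replicates 1 to 4 gave 72.3, 68.8, 121.9 and 66.6 RPKM and its glia replicates 41.7, 29.3 and 46.6 RPKM. Sox9, a SOX factor of glial fate, rose from 55.6 ± 4.75 to 75.8 ± 0.585 RPKM (log2 change 0.41 ± 0.08), with 53.5, 53.9, 62.7 and 52.5 RPKM in GPC and 76.4, 75.2 and 75.8 RPKM in glia. Nfia rose from 12.1 ± 2.49 to 23.3 ± 3.34 RPKM (log2 change 0.89 ± 0.15), with 10.4, 11.1, 15.8 and 11.2 RPKM in GPC and 22.02, 27.1 and 20.8 RPKM in glia. Sox10, a factor of the oligodendrocyte lineage, rose from 6.65 ± 0.290 to 12.5 ± 2.60 RPKM (log2 change 0.90 ± 0.13), with 6.45, 6.65, 6.44 and 7.06 RPKM in GPC and 12.96, 9.66 and 14.8 RPKM in glia. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p was 0.00638 for Sox3, 0.00069 for Sox9, 0.000637 for Nfia and 0.000142 for Sox10. Sox2, a SOX factor of neural progenitors that lies inside the noncoding gene Sox2ot, differed little, at 150.1 ± 10.1 RPKM in GPC and 181 ± 15.6 RPKM in glia, with 141, 143.6, 163.3 and 152.5 RPKM in GPC and 186, 163 and 192 RPKM in glia. Its log2 change of 0.24 ± 0.08 passed the same test (adjusted p = 0.0273), but the groups overlapped and the call ended without GPC replicate 1 (adjusted p = 0.0797), GPC replicate 2 (0.0791), GPC replicate 4 (0.0603), glia replicate 1 (0.105) or glia replicate 3 (0.109).

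**Figure D1:**
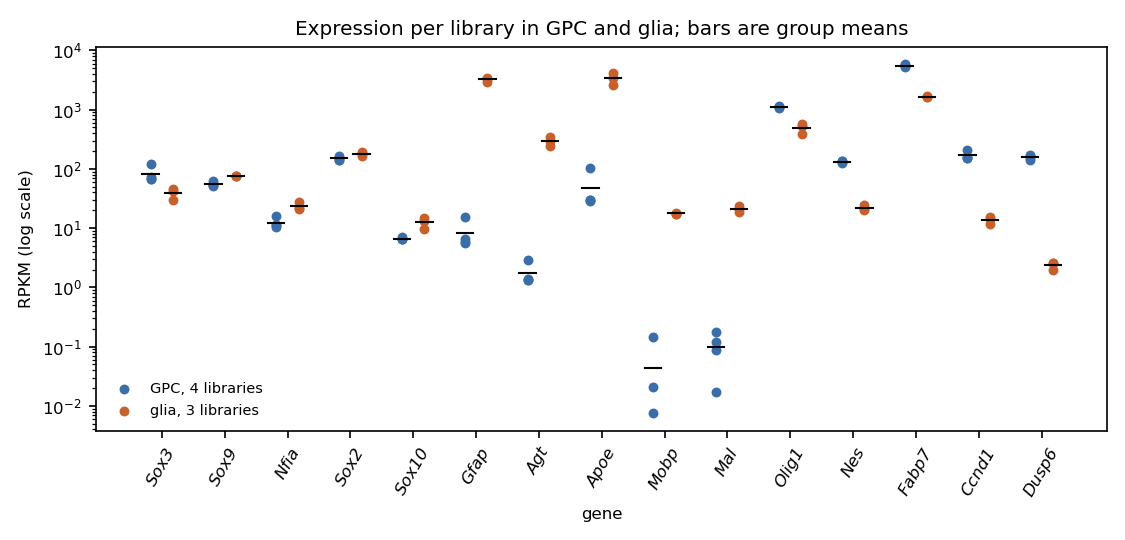
RPKM per library (log scale) for the factors and selected genes of the astrocyte, oligodendrocyte, progenitor, cell cycle and growth factor response groups, with GPC libraries in blue, glia libraries in orange and group means as bars. Gfap, Agt, Apoe, Mobp and Mal lay far higher in all 3 glia libraries and Dusp6 and Ccnd1 far lower, and the Mobp value of 0 RPKM in GPC replicate 1 is not drawn.

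Gfap, C4b, Mobp and Padi2 had the largest rises among the genes chosen by size of change. Gfap, the intermediate filament of astrocytes, rose from 8.37 ± 4.70 RPKM (SD, n = 4) to 3258 ± 291 RPKM (n = 3), a log2 change of 8.54 ± 0.44 (SE). Gfap alone took 0.802% to 0.955% of the reads in genes in glia and at most 0.00423% in GPC. Mobp and Mal, which encode myelin proteins, rose by 8.14 ± 0.28 and 7.92 ± 0.25 on the log2 scale, from 11 and 14 reads in all over the 4 GPC libraries. The other genes of this group were C4b, a complement gene with a close copy in the mouse genome whose reads may be shared (8.51 ± 0.28), Padi2, a peptidylarginine deiminase (8.13 ± 0.30), Smoc2, a secreted matrix protein (7.81 ± 0.35), Rnase1, a secreted ribonuclease (7.38 ± 0.23), and Agt, the angiotensinogen gene expressed by astrocytes (7.26 ± 0.27). Among these 8 genes the largest adjusted p was 1.49e-06, for Gfap (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Without GPC replicate 3 the log2 change was 9.35 for C4b, 9.76 for Mobp and 8.11 for Rnase1. In GPC replicates 1, 2 and 4 C4b had 0, 0 and 3 reads and Mobp 0, 1 and 1, so the size of these 2 changes is uncertain.

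The genes with the largest falls included targets and feedback inhibitors of growth factor signalling. Dusp6, a phosphatase that turns off ERK, fell from 159 ± 14.6 RPKM (SD, n = 4) to 2.36 ± 0.361 RPKM (n = 3), a log2 change of -6.05 ± 0.12 (SE). Spry4, an inhibitor of FGF signalling, changed by -5.02 ± 0.09 and Etv4, an ETS factor, by -4.53 ± 0.15. Chst7, a carbohydrate sulfotransferase, changed by -6.02 ± 0.11, and Nrgn, which encodes neurogranin, by -5.80 ± 0.28. Hmga2, a chromatin protein of progenitors, changed by -5.63 ± 0.11, Fbln2, a matrix protein, by -5.52 ± 0.08, and Pou3f1, a POU factor, by -4.74 ± 0.15. Among these 8 genes the largest adjusted p was 9.37e-08, for Nrgn (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

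Genes of differentiated glia rose together. Of 29 measured astrocyte markers 23 rose, 5 fell and 1 passed in neither direction (23 rose and 6 fell adjusted over the list alone), with a median log2 change of 1.86. Besides Gfap and Agt, the lipid carrier Apoe rose from 47.9 ± 37.1 to 3364 ± 757 RPKM, a log2 change of 6.08 ± 0.58, or 6.81 without GPC replicate 3. The astrocyte markers that fell included metabolic enzymes, the acyl-CoA synthetase Acsbg1 (222 ± 49.7 to 18.4 ± 2.23 RPKM, log2 change -3.61 ± 0.21), the glutamine synthetase Glul (373 ± 41.6 to 126 ± 4.14 RPKM, -1.60 ± 0.09) and the folate enzyme Aldh1l1 (26.7 ± 6.52 to 12.01 ± 0.810 RPKM, -1.19 ± 0.20). The other 2 were the glutamate transporter Slc1a3 (-0.75) and the receptor Fgfr3 (-1.10), named after their values were seen. The list as a whole lay above the other genes by camera, limma's competitive set test, at a preset correlation of 0.01 (adjusted p = 1.42e-08; adjusted p = 0.112 with an estimated correlation). At the preset correlation, other splits of the libraries also gave lists past the threshold, as described below, which limits each camera call given here. Of 27 markers of maturing oligodendrocytes 26 rose and none fell (26 and 0 adjusted over the list alone), with a median log2 change of 3.56. Mobp and Mal, given above, were among them, and Mobp changed by 9.76 on the log2 scale without GPC replicate 3, where few GPC reads remained. This list also lay above the other genes by camera (adjusted p = 6.41e-21; adjusted p = 0.112 with an estimated correlation, or 0.0149 without glia replicate 2). In GPC replicate 3, 21 of the 29 astrocyte markers and 20 of the 27 oligodendrocyte markers were higher than in the mean of the other GPC libraries.

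Markers of oligodendrocyte precursors were split. Of 22 measured, 15 rose and 5 fell (15 and 5 adjusted over the list alone), with a median log2 change of 0.86 and an adjusted p of 0.0107 by camera (adjusted p = 0.468 with an estimated correlation). C1ql1, a secreted complement-related protein, rose by 4.98 ± 0.38 on the log2 scale, the sialidase Neu4 by 3.11 ± 0.33 and the matrix protein Tnr by 2.96 ± 0.11. Neu4 was low throughout, at no more than 0.994 RPKM in any library. The transcription factor Olig1 fell from 1110 ± 47.8 to 496 ± 90.3 RPKM (log2 change -1.19 ± 0.12), the proteoglycan Cspg4 changed by -1.45 ± 0.23 and 2010317E24Rik, now called Sapcd2, by -1.31 ± 0.09. Olig2 (-0.99) and Ptprz1 (-0.90), named after their values were seen, were the other members that fell.

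Neural progenitor genes also went both ways, and cell cycle genes fell. Of 21 progenitor markers 7 rose and 10 fell (7 and 10 adjusted over the list alone), with a median log2 change of -0.20, and the list did not pass by camera (adjusted p = 0.339). Nes, the intermediate filament of neural progenitors, fell from 132 ± 5.77 to 21.8 ± 2.30 RPKM (log2 change -2.63 ± 0.08) and the fatty acid binding protein gene Fabp7 from 5529 ± 252 to 1659 ± 34.2 RPKM (-1.77 ± 0.07). Fut4, a fucosyltransferase gene at under 1 RPKM in every library, changed by -1.85 ± 0.36. In the other direction Lix1 rose by 4.33 ± 0.14, Dach1 by 1.503 ± 0.19 and Prom1, the gene for the surface protein CD133, by 1.503 ± 0.07. All 34 cell cycle genes fell (34 adjusted over the list alone), with a median log2 change of -2.15 (adjusted p = 9.67e-36 by camera; adjusted p = 0.112 with an estimated correlation). The cyclin gene Ccnd1 fell from 169 ± 27.7 to 13.7 ± 1.87 RPKM (-3.64 ± 0.16), and the mitotic kinase genes Cdk1 and Bub1b both changed by -2.76 (SE 0.12 and 0.13). In GPC replicate 3 only 5 of the 34 cell cycle genes were higher than in the mean of the other GPC libraries, and 15 of the 21 progenitor markers were.

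Targets and feedback inhibitors of FGF and MAPK signalling were lower in glia. The labels name EGF and FGF2 in the same text for both groups, so whether the glia were kept in these factors is not known. Of 15 measured, 12 fell and 1 rose (12 and 1 adjusted over the list alone), with a median log2 change of -2.12. By camera the adjusted p was 5.62e-18, and with all 7 libraries this was the only list that also passed with an estimated correlation (adjusted p = 0.0053), though not without GPC replicate 3 (adjusted p = 0.0596 with an estimated correlation). Dusp6 changed most, and the ETS factor gene Etv1 was the member that rose (log2 change 0.43 ± 0.09). Of 11 BMP target genes 7 rose and 1 fell (8 and 2 adjusted over the list alone), with a median of 0.94, or 1.42 without GPC replicate 3, and an adjusted p of 0.045 by camera (adjusted p = 0.465 with an estimated correlation). The BMP list did not pass without glia replicate 3 (adjusted p = 0.0714 by camera), and gave 0.0038 to 0.0456 under the other settings. Id4, an inhibitor of basic helix-loop-helix factors, rose from 6.93 ± 3.06 to 220 ± 19.3 RPKM (4.91 ± 0.28), and the BMP pseudoreceptor gene Bambi changed by -0.85 ± 0.16. Of 15 Notch pathway genes 9 fell and 2 rose (9 and 2 adjusted over the list alone), with a median of -0.57 and an adjusted p of 0.0257 by camera (adjusted p = 0.401 with an estimated correlation). The Notch list did not pass without GPC replicate 3 (adjusted p = 0.0841 by camera), and gave 0.00814 to 0.0401 under the other settings. Lfng, a glycosyltransferase that modifies Notch, changed by -1.92 ± 0.08. The effector gene Hey2 rose by 1.68 ± 0.42, or 2.36 without GPC replicate 3, and Dtx1, named after its value was seen, by 0.60.

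Genes of reactive astrocytes and markers of mesenchyme were higher in glia. Of 15 genes that astrocytes raise on injury 12 rose and 1 fell (12 and 1 adjusted over the list alone), with a median log2 change of 3.55 (adjusted p = 6.61e-08 by camera; adjusted p = 0.112 with an estimated correlation). With at least 50 counts required in 3 libraries, 11 of these genes were tested, 8 rose and the median was 1.83. Gfap rose most, and Cp, the ceruloplasmin gene, was the member that fell (log2 change -0.86 ± 0.20, groups overlapping). All 15 mesenchyme markers rose (15 adjusted over the list alone), with a median log2 change of 2.07 (adjusted p = 1.25e-08 by camera; adjusted p = 0.112 with an estimated correlation, or 0.0387 without glia replicate 3). The matrix proteoglycan gene Dcn led them, from 17.2 ± 3.62 to 140 ± 15.4 RPKM (2.96 ± 0.14). In GPC replicate 3, 11 of the 15 mesenchyme markers and 4 of the 15 reactive astrocyte genes were higher than in the mean of the other GPC libraries.

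Of the markers of other cell types that the cultures could hold, the neuronal list passed as a group and the smaller lists did not. Of 18 neuronal markers 9 rose and 1 fell (9 and 1 adjusted over the list alone), with a median log2 change of 0.52 (adjusted p = 0.00763 by camera; adjusted p = 0.193 with an estimated correlation). This median was at percentile 87.8 of random lists matched on expression, within their usual range, and at percentile 97.5 of lists matched on length. The median was 0.90 without GPC replicate 3, where 10 rose and 2 fell, and 0.83 over the 12 markers with at least 50 counts in 3 libraries. The RNA-binding protein gene Elavl3 rose from 2.81 ± 0.164 to 32.0 ± 6.91 RPKM (3.48 ± 0.15), while Nefh (3.34 ± 0.40), Syt1 (3.28 ± 0.15) and the falling Neurod1 (-1.84 ± 0.30) stayed below 6 RPKM in every library. None of the smaller marker lists passed by camera, with adjusted p of 0.545 for pluripotent cells, 0.339 for microglia, 0.628 for endothelium, 0.775 for Schwann cells and neural crest, 0.679 for endoderm and epithelium and 0.225 for ependyma. Few of their members had enough reads to be tested. In the same order the lists had 2, 2, 4, 6, 4 and 5 tested members and median log2 changes of -1.22, 1.04, -1.14, 0.47, 1.58 and 1.54, of which that of pluripotent cells was 0.92 without the filter on low counts and 0.83 without glia replicate 1. Without that filter the median was 0.45 over 9 genes for microglia, -0.05 over 9 for endothelium and 0.67 over 11 for endoderm and epithelium. It was -0.60 over 2 endothelial genes with at least 50 counts in 3 libraries, and 2.49 for endoderm and epithelium without GPC replicate 3. For pluripotent cells Klf4 rose by 0.94 and Esrrb changed by -3.37, and for microglia Tmem119 rose by 2.17. For endothelium Kdr rose by 0.92, and Emcn changed by -3.10 and Eng by -2.20. For Schwann cells and neural crest Erbb3 rose by 1.12, Mitf by 0.99 and Prx by 0.29, and Egr2 changed by -3.13, or -2.46 without GPC replicate 3. For endoderm and epithelium Gata6 rose by 3.24, or 4.17 without GPC replicate 3, Cdh1 by 2.47 and Foxa1 by 0.68, and Foxa2 changed by -1.71. For ependyma Tekt1 rose by 1.89, Dynlrb2 by 1.67, Rsph1 by 1.54 and Foxj1 by 1.13. In these small lists Eng, Mitf, Prx, Cdh1, Foxa1, Dynlrb2, Rsph1 and Foxj1 were named after their values were seen. Adjusted over each list alone, the number rising and falling was 1 and 1 for pluripotent cells, 1 and 0 for microglia, 1 and 2 for endothelium, 3 and 1 for Schwann cells and neural crest, 3 and 1 for endoderm and epithelium, and 4 and 0 for ependyma, the same as over all genes.

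**Figure D2:**
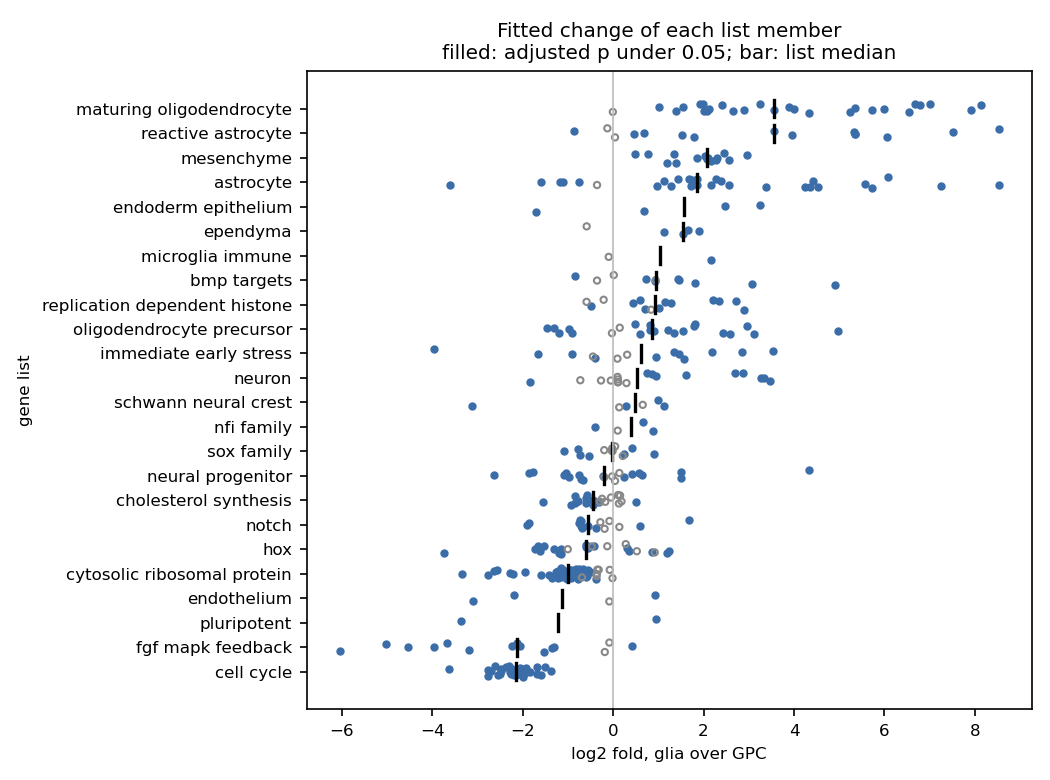
Fitted log2 change from GPC to glia (horizontal axis) of each tested member of the gene lists (vertical axis, ordered by median), with filled points for members past an adjusted p of 0.05, open points for the others and a bar at each list's median. All 34 cell cycle genes lie below 0, 26 of the 27 maturing oligodendrocyte markers lie above 0 past the threshold, and the SOX family, whose median of -0.02 changes sign under other settings, lies on both sides.

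Other gene families were examined with the same test. Of 25 Hox genes 14 fell and 5 rose (15 and 6 adjusted over the list alone), with a median log2 change of -0.59 and an adjusted p of 0.0318 by camera (adjusted p = 0.555 with an estimated correlation). The median was -0.97 over the 21 Hox genes with at least 50 counts in 3 libraries. That call ended without GPC replicate 4 (adjusted p = 0.0512), without glia replicate 2 (0.0774) and without the filter on low counts (0.052), and the other settings gave 0.000216 to 0.0485. Hoxb9, a gene of the posterior axis, fell from 45.1 ± 18.3 to 3.46 ± 0.512 RPKM (-3.75 ± 0.46), and Hoxc8 rose by 1.22 ± 0.19. Hoxd9 (1.19), Hoxd8 (0.87), Hoxd4 (0.35) and Hoxd3 (0.31), named after their values were seen, were the other Hox genes that rose, and overlapping transcripts of these clusters cannot be told apart, since whether counting used strand is not given in the sources used here. In GPC replicate 3 only 7 of the 25 Hox genes were higher than in the mean of the other GPC libraries. Of 13 SOX genes 3 rose and 4 fell (3 and 4 adjusted over the list alone; adjusted p = 0.708 by camera). Besides the factors above, Sox5 (-0.54), Sox13 (-0.73) and Sox11 (-0.77), named after their values were seen, fell. In the NFI family Nfia and Nfix (0.67, named after its value was seen) rose, Nfib changed by -0.40 ± 0.11 and Nfic, at 0.10, did not pass, also when adjusted over the list alone (adjusted p = 0.761 by camera).

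Of 14 immediate early and stress genes 7 rose and 4 fell (7 and 5 adjusted over the list alone; adjusted p = 0.239 by camera). Atf3, a stress-induced factor, rose by 3.55 ± 0.14, and Egr1, an immediate early factor, fell from 111 ± 33.0 to 7.28 ± 0.319 RPKM (-3.96 ± 0.24). Ier2 (-1.65), Hspa8 (-0.90) and Dnajb1 (-0.40), named after their values were seen, were the others that fell. Of 21 cholesterol synthesis genes 12 fell and 1 rose (12 and 0 adjusted over the list alone), with a median log2 change of -0.44 that did not pass by camera (adjusted p = 0.075). Among other settings, it passed without GPC replicate 2 (adjusted p = 0.0452), GPC replicate 4 (0.0456) or glia replicate 1 (0.0333) and without the filter on low counts (0.0369), and reached 0.230 without GPC replicate 3. In all, 20 of the 21 genes were higher in GPC replicate 3 than in the mean of the other GPC libraries. Fdft1, the squalene synthase gene, changed by 0.51 ± 0.20 (adjusted p = 0.0491 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The Fdft1 call ended without any library but GPC replicate 3, with adjusted p of 0.0874 without glia replicate 2, 0.103 without GPC replicate 1, 0.104 without GPC replicate 4, 0.105 without GPC replicate 2, 0.114 without glia replicate 3 and 0.138 without glia replicate 1.

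Genes with near-identical copies are uncertain, since their reads can be shared. Of 70 cytosolic ribosomal protein genes 63 fell and none rose (64 and 0 adjusted over the list alone), with a median log2 change of -0.99 (adjusted p = 1.44e-08 by camera; adjusted p = 0.193 with an estimated correlation). The length implied by their counts and RPKM, which can differ from that of the transcripts, had a median of 284 bp. Random genes matched on this implied length had a median log2 change of -0.29 (95% range -0.45 to -0.12). Rps29 changed by -3.34 ± 0.93, which passed (adjusted p = 0.012 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) but not without glia replicate 3 (adjusted p = 0.0545). Its RPKM was 41.2, 35.3, 3.53 and 44.4 in GPC replicates 1 to 4 and 2.61 to 3.29 in glia, so GPC replicate 3 lay near the glia level. Without GPC replicate 3 the log2 change was -3.78, and without any other GPC library Rps29 had too few reads to be tested. In GPC replicate 3, 24 of the 70 ribosomal protein genes were higher than in the mean of the other GPC libraries. Of 14 histone genes of the replication-dependent kind 10 rose and 1 fell (10 and 1 adjusted over the list alone; adjusted p = 0.112 by camera), with Hist2h3c1 at 2.89 ± 0.22 and Hist1h1c at -0.49 ± 0.10. The median of that list was 0.93, and -0.40 without the filter on low counts.

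The SOX3, SOX9 and NFIA lists in GPC differed in their number of peaks, and SOX3 and SOX9 peaks differed in the share that lay near promoters. The lists held 1367 SOX3 peaks, 2943 SOX9 peaks and 14164 NFIA peaks on the mouse build mm9. Of SOX3 peaks 33 (2.41%, 95% Wilson interval 1.72% to 3.37%) had a transcription start site (TSS) within 1 kb, and of SOX9 peaks 239 (8.12%, 7.19% to 9.16%), an odds ratio of 3.57 (2.46 to 5.34; two-sided Fisher's exact test, p = 1.59e-14). The median distance to the assigned TSS was 53.6 kb for SOX3 and 45.2 kb for SOX9. The intervals cover counting error only, and with 1 list per factor there was no replicate check. Densely filled windows of 2 Mb, with at least 20 peaks of a factor, held 10.9% of SOX3, 11.1% of SOX9 and 18.5% of NFIA peaks. The widest SOX3 peaks lay in such a region of chromosome 4, at 146899743 to 146901392 (1650 bp) and 146892784 to 146893971 (1188 bp), both assigned to Gm16503, and at 146022857 to 146024481 (1625 bp), assigned to Gm13051. The NFIA peaks of highest score lay on chromosome 9 at 102030122 to 102030422 (authors' score 1677, overlapping a SOX9 peak), chromosome 11 at 69861742 to 69862042 (1447) and chromosome 1 at 75809342 to 75809642 (1384). SOX9 peaks all had the same width and no score, so none was singled out.

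The SOX lists shared regions with each other and with NFIA. Of SOX3 peaks 299 (21.9%, 95% Wilson interval 19.8% to 24.1%) overlapped a SOX9 peak by at least 1 bp, against a mean of 1.30 in 1000 random placements, and 101 (7.39%, 6.12% to 8.90%) overlapped an NFIA peak, against 3.74. Of SOX9 peaks 835 (28.4%, 26.8% to 30.0%) overlapped an NFIA peak, against 14.7. Each of the 3 overlaps had a one-sided permutation p of 0.001, the smallest the placements can give. Random placement took no account of where reads can be mapped or of open chromatin. For none of the pairs do these values separate joint binding from regions that every antibody enriches. With peaks shifted by only 10 to 100 kb, the overlaps were 133.5, 13.999 and 28.96 times the random mean, compared with 229, 27.04 and 56.8 times with placement over whole chromosomes. SOX9 peaks that overlapped a SOX3 peak less often overlapped NFIA, at 39 of 318 (12.3%), than SOX9 peaks that did not, at 796 of 2625 (30.3%), an odds ratio of 0.32 (0.22 to 0.46; two-sided Fisher's exact test, p = 5.94e-13). SOX3 peaks that overlapped a SOX9 peak more often overlapped NFIA, at 34 of 299 (11.4%), than those that did not, at 67 of 1068 (6.27%), an odds ratio of 1.92 (1.20 to 3.01; Fisher's exact p = 0.00552). NFIA peaks that overlapped SOX9 peaks had a median score of 29, and the others 16. With NFIA peaks ranked by score and divided into 10 equal parts, 32.1% of the part with the highest scores overlapped a SOX9 peak, against 7.56% or less in every other part.

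**Figure D3:**
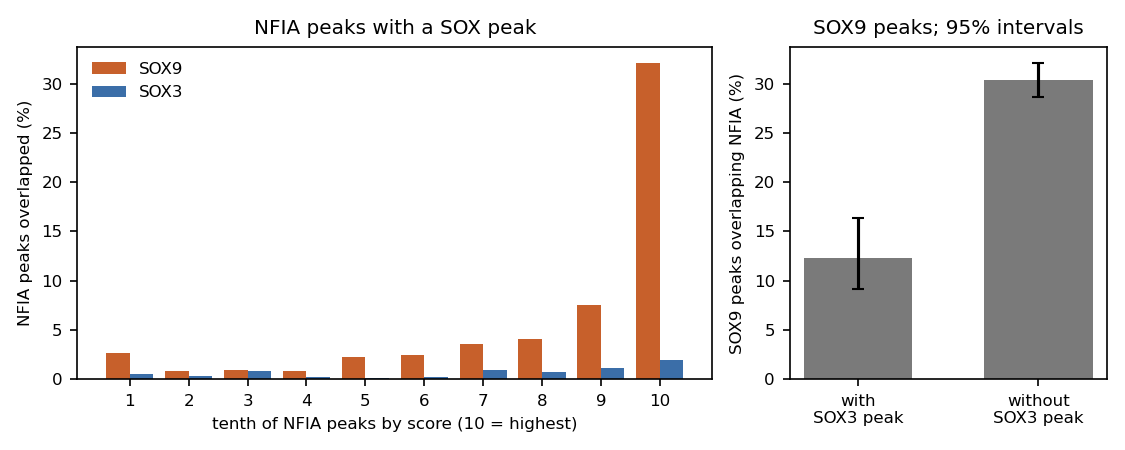
Left, share of NFIA peaks (%) overlapping a SOX9 (orange) or SOX3 (blue) peak in each of 10 equal parts of the NFIA list ranked by the authors' score, with tied scores split by position. Right, share of SOX9 peaks (%) overlapping an NFIA peak among those with and without a SOX3 peak, with 95% Wilson intervals, at 12.3% and 30.3%.

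Peaks of SOX3 and SOX9 lay near rising and falling genes about alike. With peaks assigned to the TSS the authors gave, within 100 kb, 446 of 4788 rising genes (9.31%) had a SOX9 peak, against 314 of the 4019 genes that did not pass (7.81%), an odds ratio of 1.21 (95% interval 1.04 to 1.41; adjusted p = 0.053). For falling genes it was 422 of 4777 (8.83%), an odds ratio of 1.14 (0.98 to 1.34; adjusted p = 0.089). SOX3 peaks lay near 208 rising genes (4.34%) and 204 falling genes (4.27%), against 3.56% of the genes that did not pass, with odds ratios of 1.23 (0.99 to 1.54) and 1.21 (0.97 to 1.51), both at an adjusted p of 0.089. None of these 4 two-sided Fisher's exact tests passed after Benjamini-Hochberg adjustment. At 2-fold or more all 4 passed, with odds ratios of 1.40 (SOX3, rising), 1.53 (SOX3, falling), 1.33 (SOX9, rising) and 1.48 (SOX9, falling), and within 20 kb 3 of the 4 passed, all but SOX3 near rising genes. Compared directly, rising and falling genes did not differ, with odds ratios of 1.02 for SOX3 (95% interval 0.83 to 1.25; Fisher's exact p = 0.88) and 1.06 for SOX9 (0.92 to 1.22; p = 0.413). The share of genes that rose was 34.9% of 12066 genes with neither peak, 38.7% of 336 with SOX3 only, 38.2% of 963 with SOX9 only, 35.6% of 219 with both, and 38.3% of 274 with a SOX9 peak that overlapped NFIA. The share that fell was 35.1%, 37.2%, 35.6%, 36.1% and 32.8%. In a logistic regression with both SOX factors, overlap of the SOX9 peak with NFIA and mean expression, the odds ratio of rising was 1.24 (95% interval 1.04 to 1.48) for SOX9, 1.25 (0.995 to 1.56) for SOX3 and 0.919 (0.656 to 1.29) for the NFIA overlap. For falling it was 1.11 (0.927 to 1.33) for SOX9, 0.979 (0.778 to 1.23) for SOX3 and 0.872 (0.612 to 1.24) for the NFIA overlap, and these intervals were not adjusted over the 6 terms.

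SOX3 and SOX9 peaks lay near progenitor and astrocyte genes more often than near other tested genes. Genes far from their neighbours can collect more peaks. That distance was not held constant here or for the changed genes above, so its part in these odds ratios is not known. Of 48 two-sided Fisher's exact tests of list and factor 7 passed after Benjamini-Hochberg adjustment. SOX3 peaks were assigned to 8 of 21 neural progenitor genes (among them Fabp7, Msi1, Notch1, Pax6, Pou3f3, Sox2 and Sox21; odds ratio 14.6, 95% interval 5.23 to 38.3; adjusted p = 4.5e-05) and to 6 of 29 astrocyte genes (Fgfr3, Id3, Mlc1, Slc1a3, Sparcl1 and Ttyh1; 6.18, 2.05 to 15.7; adjusted p = 0.0154), compared with about 4.05% of other tested genes. SOX9 peaks were assigned to 7 of 21 progenitor genes (Cdh2, Fabp7, Notch1, Pax6, Pou3f2, Sox21 and Vim; 5.27, 1.80 to 13.99; adjusted p = 0.0174) and to 8 of 29 astrocyte genes (Aldh1l1, Aqp4, Gfap, Mt3, Ndrg2, Slc1a3, Sparcl1 and Ttyh1; 4.02, 1.54 to 9.47; adjusted p = 0.0252), compared with about 8.66% of other tested genes. SOX9 peaks also lay near 6 of 18 neuronal genes (5.27, 1.62 to 15.2; adjusted p = 0.0255) and 6 of 14 histone genes (7.90, 2.26 to 26.0; adjusted p = 0.0154), and near 0 of 70 ribosomal protein genes (upper limit of the odds ratio 0.566; adjusted p = 0.0286). Without densely filled windows none of the 14 histone genes had a SOX9 peak (adjusted p = 1), and the neuronal call ended (5 genes, adjusted p = 0.0725, Fisher's exact test). Within 20 kb the SOX9 calls ended for progenitor genes (3 genes, odds ratio 3.71, adjusted p = 0.286), neuronal genes (4 genes, 0.0621) and ribosomal protein genes (0.304), by Fisher's exact test, while the other 4 calls passed. For 6 of 22 oligodendrocyte precursor genes with SOX9 peaks the adjusted p was 0.0505, and for 3 of 11 BMP target genes with SOX3 peaks it was also 0.0505. With all genes of the table as background both passed (adjusted p = 0.0199 for 6 of 22 and 0.0378 for 3 of 13, Fisher's exact test). The members listed here were named after their peaks were seen.

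Loci chosen after their peaks were seen show the layout on mm9. A SOX9 peak on chromosome 11 at 102759555 to 102760155 lay 1.41 kb upstream of the Gfap TSS. Peaks of both SOX factors lay together 40.6 kb upstream of Fabp7 on chromosome 10 (SOX3 at 57463979 to 57464101 and SOX9 at 57463787 to 57464387). Olig1 had 1 SOX3 peak on chromosome 16 at 91263075 to 91263345 and 5 SOX9 peaks, of which the peak at 91263014 to 91263614 overlapped it, 6.7 kb upstream. Some of the SOX9 peaks of Olig1 overlapped each other, so they mark fewer regions than peaks. Sox2 had 2 SOX3 peaks, at 34457954 to 34458337 and 34552792 to 34552973 on chromosome 3, and no SOX9 peak. Id4 had 1 SOX3 peak and 2 SOX9 peaks that overlapped each other, on chromosome 13 about 63 kb downstream. None of these peaks overlapped an NFIA peak. Aldh1l1 had 2 SOX9 peaks on chromosome 6, of which the peak at 90481727 to 90482327 overlapped NFIA, and Klf4 had 1 SOX9 peak, on chromosome 4 at 55549920 to 55550520, that overlapped NFIA. Whether a peak lay in an exon, intron or between genes was not analysed here.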

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

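The tests on GPC replicate 3, on the mesenchyme list and on the SOX9 and NFIA overlap were chosen only after those results were seen, and the counts of other splits of the samples were laid out before the data were examined.

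GPC replicate 3 stood apart from the other 3 GPC libraries. It had 22.4 M reads in genes (22439837), against 12836998 to 13037426 in the others. Among the 70 named genes, 21 had a GPC library far from the others, and in 18 of them it was replicate 3. In it RPKM was higher than in the other GPC libraries for Sox3 (122, others 66.6 to 72.3), Sox9 (62.7, others 52.5 to 53.9), Nfia (15.8, others 10.4 to 11.2), Gfap (15.4, others 5.64 to 6.52), Mobp (0.146, others 0 to 0.0207), Agt (2.90, others 1.31 to 1.40), Apoe (103.6, others 28.9 to 29.9), Ccnd1 (210.1, others 151 to 158), Id4 (11.5, others 5.11 to 5.78), Hey2 (6.18, others 1.56 to 2.24), Egr2 (7.56, others 2.27 to 2.68), Fdft1 (124, others 71.1 to 76.3) and Egr1 (160.3, others 91.3 to 97.8). It was lower for Acsbg1 (148, others 241 to 254), Aldh1l1 (17.0, others 29.5 to 30.4), Cspg4 (3.54, others 6.46 to 7.00), Cp (3.40, others 5.38 to 5.71) and Hoxb9 (17.9, others 52.7 to 56.7). In GPC replicate 4 Tnr was at 2.89 (others 2.49 to 2.56) and Prom1 at 12.6 (others 13.6 to 13.7), and in GPC replicate 2 the gene 2010317E24Rik was at 23.1 (others 25.1 to 25.5). Chance sets a library apart in about 1 in 20 groups by the measure used, and over all tested genes it was replicate 3 in 8.60% and each other GPC library in 0.552% to 0.861%.

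Not every list that was higher in GPC replicate 3 rose in glia. In this library 20 of 21 cholesterol synthesis genes and 15 of 21 progenitor markers were higher than in the mean of the other GPC libraries. Only 5 of 34 cell cycle genes and 7 of 25 Hox genes were. The share over all tested genes is not given here. Of 87 genes high in glia, 89.7% were higher in GPC replicate 3 than in the other GPC libraries, so RNA of cells like the glia may be present in it. Such RNA would raise each of these genes by about 1 common share of its glia level, but the implied share was 0.288% for Gfap, 2.23% for Apoe and 39.4% for Ttyh1, and 35.6% of the genes lay below 0.5 of the median share of 2.44%, which argues against it as the only cause. Deeper sequencing of this library was tested by thinning it to the depth of GPC replicate 1, after which it stood apart at 9.09% of genes, against 8.77% at full depth, which argues against depth. A culture that differed in its state, with fewer cell cycle and Hox transcripts, stays open and was not tested, since the labels name no difference between the GPC samples.

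All 15 mesenchyme markers rose in glia. A smaller share of glial cells would raise the markers of every other cell type alike if glial cells expressed none of them. The mesenchyme list had a median log2 change of 2.07 and the neuron list 0.52 (two-sided permutation p = 0.00955). Without GPC replicate 3 the medians were 2.21 and 0.90 (permutation p = 0.0433, the highest p of all settings). These values argue against a dilution that raises both lists alike. Glial cells that express a neuronal marker could hold down its rise, so dilution as such is not excluded. A larger share of mesenchymal cells could raise the markers by a common factor, while their log2 changes ran from 0.48 to 2.96, a heterogeneity Q per degree of freedom of 30.0 (10.3 over the 5 most abundant members), which goes against 1 common factor for all members. Since no member fell, and other cells that express a member could hold down its rise, a change in cell share and a change of expression within glia cannot be told apart. The levels of the leading marker Dcn, 17.2 RPKM in GPC and 140 RPKM in glia, leave both open, although the sort for A2B5, in the protocol given for both groups, would remove mesenchymal cells that lack this antigen before the cells were grown on.

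SOX9 peaks overlapped NFIA peaks 56.8 times as often as randomly placed peaks. Regions densely filled with peaks are a candidate cause. Without windows of at least 20 peaks in 2 Mb, 674 of 2616 SOX9 peaks (25.8%) overlapped NFIA, against 28.4% of all SOX9 peaks. The ratio to random placement was then 62.3. Such windows held only 11.1% of SOX9 peaks, so their removal could not have ended the overlap. The values show only that most of the overlap lay outside these windows. Regions that every antibody enriches could also bring the lists together, and SOX9 peaks with a SOX3 peak would then overlap NFIA more often than those without. Their odds ratio was 0.32, which goes against this, while for SOX3 peaks with and without a SOX9 peak it was 1.92, which goes with it, so this explanation cannot be told apart from joint binding. No biological explanation was tested, since no sample lacks a factor.

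Of the 35 ways to split the 7 libraries into 4 and 3, only the real split, 1 of 35, gave as many as 9568 changed genes, and the highest other split, GPC replicates 1, 2 and 4 against the rest, gave 3496. For genes changed at least 2-fold it was also 1 of 35, with 3491 genes and 1648 in the highest other split. With 35 splits, 1 of 35 is the smallest share possible, so these 2 counts go against chance only to that degree. The splits also cannot show whether the replicates were technical. For the number of gene lists past the threshold, 12, as many were reached in 6 of 35 splits and the highest other split gave 14, so chance cannot be excluded for that number. Every other split gave at least 3 lists, also where 0 genes changed. A camera call of a single list at the preset correlation is therefore open to the same limit.

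The NFIA list held 13 peaks on the mitochondrial chromosome, where neither SOX list had a peak, with a median score of 335 against 16 over the whole list.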

How the results depend on the processing

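The tests without densely filled windows, with mean expression as a covariate, on SOX9 peaks overlapping NFIA, and near gene lists within 20 kb were chosen only after the results were seen. Without each library in turn, 8512 to 10273 genes changed and 3474 to 3638 changed at least 2-fold, and DESeq2, its size factors, both filters and the replicate block gave 8367 to 10118. Of these, the filters moved the number changed at least 2-fold from 3491 to 2559 (at least 50 counts in 3 libraries) and 4212 (no filter), and the rest gave 3478 to 3496, with no call in the opposite direction in any of them. Replicate numbers did not pair GPC with glia (correlations of deviations -0.05, 0.32 and 0.10, and only glia replicate 2 correlated best with its own number), and the replicate block, which also left out GPC replicate 4 since no glia library has that number, gave 8943 changed genes, against 8951 without GPC replicate 4 alone. The cholesterol list passed by camera in both (adjusted p = 0.0219 with the block, 0.0456 without it), and with an estimated correlation FGF and MAPK feedback had an adjusted p of 0.238 with the block and 0.0153 without it. Of 827 alternative values for the 70 named genes 814 kept their direction and side of the threshold, and 13, for Sox2, Fdft1 and Rps29, no longer passed. Of 286 for gene lists 259 were the same, 16 no longer passed, 5 now passed and 6 changed sign. The number of lists past the threshold was 11 to 13 without each library, and 1 (FGF and MAPK feedback) with an estimated correlation, where correlated members widen the error. None of the lists whose median changed sign passed in either case. These were pluripotent cells (0.92 without the filter on low counts, -1.27 to 0.83 without each library, -1.22 in the report), the SOX family (0.0153 with at least 50 counts in 3 libraries, -0.0758 to 0.0739 without each library, -0.02 in the report) and histones (-0.40 without the filter, 0.93 in the report). The filters change which genes are tested, and the cause was not tested further. For binding near changed genes, odds ratios passed the threshold at 2-fold or more (SOX3 rising 1.40, SOX3 falling 1.53, SOX9 rising 1.33, SOX9 falling 1.48), within 20 kb (SOX3 falling 1.51, SOX9 rising 1.36, SOX9 falling 1.38), with the SOX3 list halved by width (falling 1.42) and with mean expression as a covariate (SOX3 rising 1.33, SOX9 rising 1.26), and the odds ratio was 0.958, not passing, for SOX9 peaks overlapping NFIA near falling genes. With factors combined at 2-fold or more, the SOX3 term was 1.70 for rising genes and 1.36 (not passing, from 0.979) for falling genes, and the SOX9 term 1.42 for falling genes. Within 20 kb 4 pairs of list and factor passed (7 within 100 kb). For these binding values the cause was not tested. With 5 kb in place of 1 kb, 8.56% of SOX3 and 14.1% of SOX9 peaks lay near a TSS, as the wider distance must give. Overlaps stayed at a permutation p of 0.001, the smallest possible, in all alternatives, at 13.999 to 433 times random. Not run were motif tests, NFIA near genes, gene territories as a covariate, any peak within 50 kb, the 8 combinations of 3 factors, reduced SOX9 lists and a split into genic and intergenic peaks. Depth limits genes with few reads, such as Mobp and C4b in GPC.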

Other observations

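The counts of peaks by region and their scores were chosen only after the results were seen.

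Histone genes stood out in the SOX9 list. On chromosome 13 from 20 to 24 Mb, where the Hist1 genes lie, there were 92 SOX9 peaks, 61 of them overlapping an NFIA peak, but 4 SOX3 peaks. Of the 92 SOX9 peaks 43 were assigned to Hist1 genes, and 29 of these lay within 1 kb of the TSS. The NFIA peaks there numbered 76, with a median score of 38, against 16 over the whole NFIA list. With all genes as background, 26 of 67 replication-dependent histone genes had a SOX9 peak within 100 kb (odds ratio 8.77, 95% interval 5.14 to 14.7; two-sided Fisher's exact test, adjusted p = 3.45e-12), though neighbouring genes of a cluster are not independent. Replication-dependent histone transcripts lack poly(A) tails, so their RNA levels depend on how the RNA was selected.

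Peaks were unevenly spread along some chromosomes. The X chromosome held 1055 NFIA peaks (7.45%), of which 327 lay between 120 and 122 Mb and 218 between 122 and 124 Mb, and the Y chromosome held 237. SOX3 had 3 peaks on X (0.219% of its list), and SOX9 had 68 on X (2.31%) and 4 on Y. On chromosome 4, 38 SOX3 peaks lay between 144 and 146 Mb and 27 between 146 and 148 Mb.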
